A study of Mus musculus with 22 samples.

How the data were processed

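Gene expression was measured by RNA sequencing in 22 mouse liver tumours raised in C57BL/6 mice by hydrodynamic tail-vein injection, in which a large volume of plasmid solution is pushed into the tail vein so that hepatocytes take the plasmids up. Every tumour carried MYC, and the second driver was either loss of p53 or a β-catenin (CTNNB1) construct. Each driver pair was combined either with luciferase alone (luc) or with lucOS, luciferase joined to model antigen peptides that T cells can recognise. The libraries were made from total RNA with a TruSeq kit, per the labels' protocols, which do not state whether strand was kept. Reads of overlapping and antisense genes can therefore not be told apart.

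The values came from 2 tables of gene-level signal that the authors deposited, 1 for a first set of 12 tumours and 1 for a second set of 10 tumours. TopHat2, featureCounts and DESeq2 and the mouse build mm10 are named in the submitters' processing notes, without versions or options. In both tables the deposited signal was a whole number of reads divided by 1 factor per sample, since 100% of the values were whole multiples of the smallest value of their sample within a tolerance of 0.01 reads. The reads recovered in this way were used for depth, for floors and for the count-based alternatives. The tables were scaled separately, so every test compared tumours within 1 table only, and the sets were compared only through their fold changes.

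The first table held 33068 RefSeq transcripts. For each gene the transcript with the highest mean stood for the gene, which gave 24063 genes, of which 4914 had more than 1 transcript. Of the symbols there, 53 had been turned into dates and were restored from the RefSeq accession. The second table held 24046 symbols, and 27 that had been turned into date numbers were left out, which gave 24019 genes. Total reads over genes per tumour ran from 33.706 M to 54.873 M reads in set 1 and from 33.551 M to 50.116 M reads in set 2. Floors for genes at 0 were set at 3 reads per library. Floors cover counting error only, because reads without molecular identifiers are not independent molecules. Hba-a1 and Hba-a2 had identical values, and the Raet1 genes are near-identical copies, so their separate values are uncertain. Both Hba genes entered the red blood cell list as separate members, so its tests and counts include the same values more than once. Positions are those of GENCODE vM21 on GRCm38, the same assembly as mm10.

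Groups came from the genotype labels: lucOS p53 (3 tumours), luc p53 (3), lucOS β-catenin (2) and luc β-catenin (4) in set 1, and lucOS p53 (4), luc β-catenin (3) and lucOS β-catenin (3) in set 2. The labels do not say that each tumour came from its own animal, so the p-values of single genes measure the spread between these tumour samples. In 7 contrasts, β-catenin was compared with p53 within lucOS (both sets) and within luc (set 1), lucOS with luc within p53 (set 1) and within β-catenin (both sets), and in set 1 the driver difference with lucOS was set against that with luc (the interaction). Genes with a value of at least 10 in at least 2 tumours (set 1) or 3 tumours (set 2) were kept. Log2 of the value plus 1 was fitted with limma 3.58.1 in R 4.3.3, with the trend option, all groups of a set in 1 fit and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. All adjusted p-values of single genes are limma's unless another tool is named. Reported means and SDs are of the deposited values, and fold changes come from the fit on the log scale. Bounds given as at least a fold instead divide the mean of the other group by the floor.

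Before the data were examined, 27 lists with 376 genes in all were written down: Wnt/β-catenin targets, pericentral, periportal and mature hepatocyte genes, p53 targets, fetal liver genes, bile duct markers, T cell, cytotoxic and NK cell, checkpoint and regulatory T cell, dendritic cell, B and plasma cell, macrophage and neutrophil markers, chemokines, MHC class I, MHC class II, type I interferon and interferon γ genes, endothelial and stellate cell markers, cell cycle, ribosome biogenesis, lipid synthesis, red blood cell, acinar pancreas and sex-linked genes. In set 1, 374 of the list genes were matched, and in set 2, 372. Lists with at least 5 kept members were tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with the correlation estimated from the data. At the preset value the genes of a list count as nearly independent, so these p-values do not measure the spread between tumours. The score of a list in a tumour is the mean of its members' log2 values, and scores were compared with two-sided exact permutation tests.

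The genes named were chosen by a rule also fixed at that point. It takes Myc, Ctnnb1, Trp53 and Ccl5; the 8 genes per direction with the largest fold change in the driver contrasts, or 5 in the others, among called genes with a mean of at least 100 in the higher group; and up to 4 members per list with the smallest p. The text names some of these. Genes named outside this rule are said to have been chosen after their values were seen.

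The alternatives were pseudocounts of 0.5 and 5, no filter and a stricter filter at 50, rescaling by trimmed mean of M values (TMM), fitting only the groups compared, each tumour left out in turn, the set 2 tumours named JAX alone, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and the estimated correlation for lists. The mean of a gene's transcripts, and log values centred on the sample median, were chosen after seeing the data. On recovered reads edgeR's quasi-likelihood test called 418, 1785 and 2230 genes in the driver contrasts with lucOS in set 1, luc in set 1 and lucOS in set 2, and 0 in each of the other 4 contrasts. The code was tested on simulated data in which 200 genes per contrast were changed. These were drawn only from genes with a mean value of at least 50, so the shares recovered do not cover lower genes. At 8-fold, 74% of changed genes were recovered for the lucOS driver contrast of set 1 (15930 genes run), 81% for luc in set 1 (15911) and 88% for lucOS in set 2 (15461). For the antigen contrasts 80% were recovered in p53 tumours of set 1 (15916), 80% in β-catenin tumours of set 1 (15902) and 78% in those of set 2 (15453), and for the interaction 57% (15913). At 2-fold the recovered shares were 2%, 11%, 17%, 6%, 6%, 17% and 0% in the same order.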

Results

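Transcript levels were measured in 22 MYC-driven mouse liver tumours in 2 sets that were processed separately. Set 1 held 12 tumours: 3 with p53 loss and lucOS, 3 with p53 loss and luc, 2 with β-catenin and lucOS, and 4 with β-catenin and luc. Set 2 held 10 tumours: 4 with p53 loss and lucOS, 3 with β-catenin and lucOS, and 3 with β-catenin and luc. The series concerns whether β-catenin activation lets liver tumours escape immune recognition, and none of the tumours had been treated. Total reads over genes per tumour ran from 33.706 M to 42.794 M (lucOS β-catenin), 42.469 M to 49.593 M (lucOS p53), 40.941 M to 50.65 M (luc β-catenin) and 36.026 M to 54.873 M (luc p53) in set 1. The corresponding ranges in set 2 were 45.586 M to 50.116 M (lucOS β-catenin), 33.551 M to 40.754 M (lucOS p53) and 41.106 M to 48.022 M (luc β-catenin). Between 17307 and 18310 genes were detected per tumour in set 1 and between 17529 and 18170 in set 2. The ribosomal RNA gene Rn45s took 8.90% of the reads of luc p53 tumour 1, more than in any other tumour of set 1. All sample names in set 1 begin with AL. In set 2, p53 tumours 1 to 3 have names beginning with AL, and p53 tumour 4 and the 6 β-catenin tumours have names beginning with JAX. Xist, the transcript of the inactive X chromosome, had values from 33320 to 78910 in all 22 tumours. Reads of the 4 Y-linked genes of the sex-linked list numbered 0 in every set 1 tumour and every set 2 p53 tumour, and from 1 to 12 in the set 2 β-catenin tumours.

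The targeted genes were examined first. Trp53 (chromosome 11, 69580359 to 69591873, plus strand, mm10) was lower in the p53 tumours of both sets, and every β-catenin tumour lay above every p53 tumour of its set. In set 1 the p53 tumours had Trp53 values from 1423 to 2280 and the β-catenin tumours from 3296 to 4994, and in set 2 the ranges were 1345 to 2223 and 2631 to 4405. The β-catenin minus p53 difference of Trp53 was 1.27 on the log2 scale among luc tumours (adjusted p = 0.00346, n = 4 and 3). Among lucOS tumours it was 1.30 in set 1 (adjusted p = 0.0214, n = 2 and 3) and 0.95 in set 2 (adjusted p = 0.0237, n = 3 and 4). The set 1 lucOS call was lost without p53 tumour 1 (adjusted p = 0.0572) or β-catenin tumour 1 (0.0983). That of set 2 was lost without p53 tumour 2 (0.0526), p53 tumour 3 (0.0521) or β-catenin tumour 1 (0.0629), and in the tumours named JAX alone (log2 1.08, adjusted p = 0.44), where 1 p53 tumour is left. Ctnnb1 (chromosome 9, 120929216 to 120960507, plus strand) was not called in any driver contrast, with log2 differences of -0.35 (adjusted p = 0.36), -0.47 (0.101) and -0.22 (0.343) for lucOS in set 1, luc in set 1 and lucOS in set 2. Myc (chromosome 15, 61985391 to 61990374, plus strand) was not called either, with 0.55 (adjusted p = 0.642) among luc tumours, 0.32 (0.737) in set 2 and -0.06 (0.978) among set 1 lucOS tumours, the last turning to 0.09 under TMM. The labels do not give the sequences of the injected constructs, so these values need not include all of their transcripts.

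**Figure D1:**
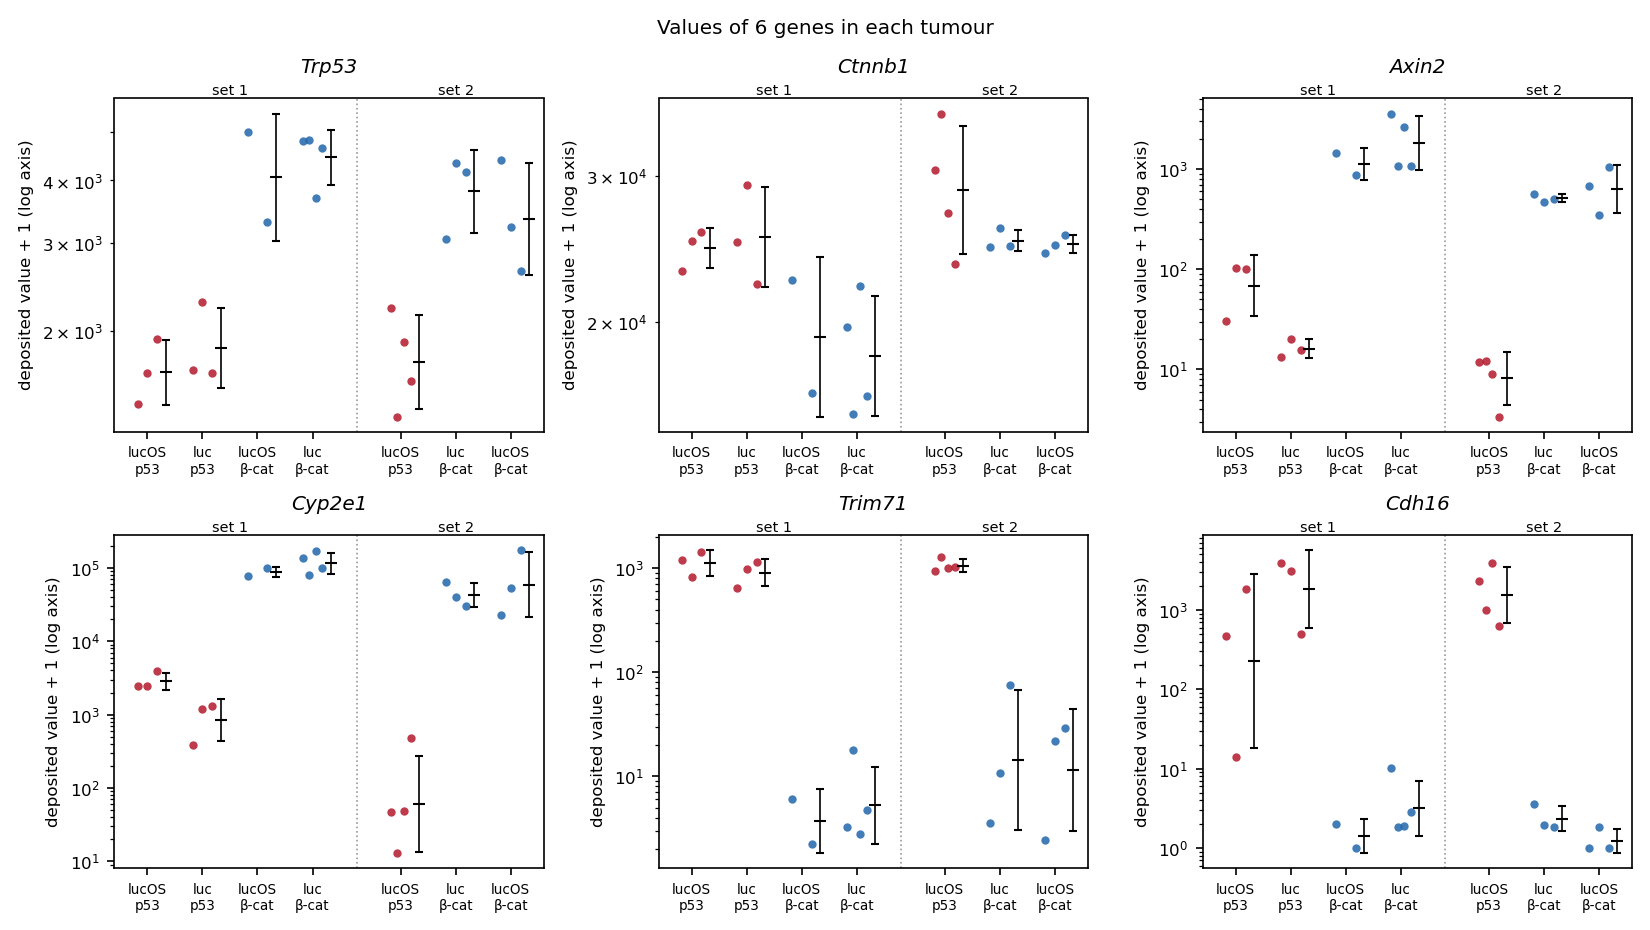
Deposited value plus 1 on a log axis for Trp53, Ctnnb1, Axin2, Cyp2e1, Trim71 and Cdh16 in each tumour, by group. Points are tumours (red p53, blue β-catenin), and the black dash and bar are the mean ± SD of the log2 values; for Axin2 the set 2 p53 tumours lie from 2.376 to 11.04 and the β-catenin tumours from 349.1 to 1047.

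Among luc tumours of set 1, the comparison of 4 β-catenin with 3 p53 tumours asked how the driver changes the tumour without the antigen. Wnt feedback and target genes rose with β-catenin. Axin2, a negative feedback gene of the pathway, stood at 2092 ± 1242 (SD, n = 4) against 15.4 ± 3.60 (n = 3; log2 6.82, adjusted p = 0.000124). Notum, a secreted Wnt inhibitor, stood at 5334 ± 4572 against 12.6 ± 4.88 (log2 8.36, adjusted p = 0.000124). Genes that mark hepatocytes around the central vein rose as well, with Cyp2e1 at 121000 ± 39570 against 954 ± 491 (log2 7.11, adjusted p = 1.1e-05). The carboxylesterase gene Ces1f stood at 5319 ± 3195 against 7.11 ± 11.2 (log2 10.29, adjusted p = 0.000144). Cyp4a10 and Cyp4a14, fatty acid hydroxylase genes, rose by 9.56 and 9.65 on the log2 scale (adjusted p = 0.000144 and 0.000917). The p53 tumours had more of Trim71, a stem cell RNA-binding protein (6.21 ± 7.29 in β-catenin against 927 ± 259 in p53, log2 -7.42, adjusted p = 0.000144). They also had more of the kidney and epithelial genes Cdh16 (3.17 ± 3.96 against 2514 ± 1787, adjusted p = 0.00299) and Pax8 (2.22 ± 3.11 against 923 ± 528, adjusted p = 0.00648). Onecut3, a liver and nerve cell transcription factor gene, was at 0 in all β-catenin tumours, against 611 ± 694 in p53 tumours. Its mean was at least 214-fold lower, a bound that rests on widely spread p53 values. All of these calls held with each tumour left out.

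Of the Wnt targets among luc tumours, 9 of 12 were higher, 0 lower and 3 not called (9 when adjusted over the list alone), with a median log2 difference of 3.82 and a camera adjusted p = 8.9e-12. Of the pericentral genes 12 of 13 were higher (13 over the list alone), with a median of 6.87 and adjusted p = 3.26e-18. Both held with an estimated correlation (adjusted p = 0.0308 and 0.0151). The 8 other called lists did not (0.114 to 0.897). The p53 targets had 5 higher, 1 lower and 14 not called (7 and 1 over the list alone, camera adjusted p = 0.000469). Among them were Ccng1 at 3174 ± 445 against 1171 ± 122 and Eda2r at 441 ± 144 against 17.7 ± 15.5 (adjusted p = 0.00322 and 0.00759). Mature hepatocyte genes had 4 of 17 higher and 0 lower (8 over the list alone, adjusted p = 6.84e-05), among them Cyp3a11 (log2 3.64) and Tat (3.46). Macrophage markers had 1 of 16 higher (0 over the list alone, median 1.13, adjusted p = 0.000246) and type I interferon genes 1 of 18 higher (1 over the list alone, median 0.678, adjusted p = 0.000518). Ribosome biogenesis genes had 6 of 19 lower and 0 higher (10 over the list alone, median -0.786, adjusted p = 0.000518), and lipid synthesis genes 3 of 14 higher (4 higher and 1 lower over the list alone, adjusted p = 0.0268). The lipid call was lost without p53 tumour 2 (0.0681) or β-catenin tumour 2 (0.06) or 4 (0.0589).

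Cytotoxic and NK cell genes were lower in the luc β-catenin tumours, with 3 of 13 called lower, 0 higher and 10 not called (4 over the list alone), a median of -1.33 and a camera adjusted p = 0.0165 (adjusted p = 0.776 with an estimated correlation, and 0.121 without p53 tumour 3). Granzyme genes, which encode killer cell proteases, stood at 7.60 ± 3.04 against 77.2 ± 44.9 (Gzma, adjusted p = 0.0169) and 9.98 ± 4.59 against 87.5 ± 47.4 (Gzmb, 0.0155). Their calls were lost without p53 tumour 1 (0.0616 and 0.0685) or p53 tumour 3 (0.0573 and 0.0507). T cell markers had 2 of 15 lower (0 over the list alone, camera adjusted p = 0.21). Ccl5 (chromosome 11, 83525778 to 83530518, minus strand), a chemokine that attracts T cells and dendritic cells, was not called (35.7 ± 4.36 against 84.7 ± 51.2, log2 -1.06, adjusted p = 0.233). Dendritic cell markers had 1 of 14 lower (1 over the list alone), with a median of -0.248 while the camera test pointed upward (adjusted p = 0.565). Chemokine genes (1 of 20 lower, adjusted p = 0.797), checkpoint genes (0 of 12, adjusted p = 0.641) and neutrophil markers (0 of 10, adjusted p = 0.447) were not called as lists. Neither were MHC class I (2 of 15 higher, adjusted p = 0.0528), MHC class II (0 of 11, adjusted p = 0.386), interferon γ genes (1 of 13 higher, adjusted p = 0.106) and B cell markers (1 of 7 lower, adjusted p = 0.797), the last with a median of 0.384 and a mean of -0.132. Cell cycle genes had 1 of 20 lower (0 over the list alone, median -0.539, adjusted p = 0.038), a list call lost without p53 tumour 1 (0.105), p53 tumour 3 (0.118) or β-catenin tumour 3 (0.23). Fetal liver genes (4 of 12 lower, adjusted p = 0.218), bile duct markers (2 of 8 lower, adjusted p = 0.116, but 0.0415 under TMM), stellate cell genes (0 of 15, adjusted p = 0.326) and red blood cell genes (0 of 7, adjusted p = 0.541) were not called. Periportal genes were not called either (1 higher and 2 lower of 12, adjusted p = 0.899), and their median of -0.101 turned to 0.0873 under TMM. Endothelial markers (0 of 13, adjusted p = 0.635) had a median of -0.181 that turned to 0.00661 under TMM, and a mean of 0.239. The 4 kept acinar pancreas genes had 1 lower, with a median of 0.191 and a mean of -0.509, too few for a list test.

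Over all genes of the luc comparison, limma called 2431 of 16108, 956 higher and 1475 lower with β-catenin. TMM rescaling called 1901, 1221 higher and 680 lower, of which 1636 were shared. The median log2 difference of all genes was -0.198 as deposited and -0.0112 under TMM. With each tumour's log values centred on their own median, 1968 genes were called, 1068 higher and 900 lower. The median difference was then -0.0926. For lucOS the median was -0.147 in set 1 and -0.161 in set 2, against 0.000351 and -0.00439 under TMM, so a deposited difference of about that size marks no change against the bulk of genes. By edgeR 1785 genes were called in the luc comparison and by DESeq2 3303. The count was 812 without p53 tumour 1, 982 without p53 tumour 2, 1604 without β-catenin tumour 2 and 1208 without β-catenin tumour 3.

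Among lucOS tumours of set 1, which carry the antigen, 2 β-catenin tumours were compared with 3 p53 tumours. Cyp2e1 again rose, to 88550 ± 15130 (n = 2) from 2931 ± 836 (n = 3; log2 4.94, adjusted p = 0.00115). Trim71 was lower at 3.18 ± 2.74 against 1148 ± 309 (log2 -8.24, adjusted p = 0.00115). Dao, the D-amino acid oxidase gene, was at 0 in both β-catenin tumours and at least 65-fold lower, against 221 ± 124. Kl, the klotho gene, was also at 0, against 1556 ± 2060 in p53 tumours. Its mean was at least 457-fold lower, a bound that rests on widely spread p53 values. The calls of these genes held with each tumour left out. Axin2 (1162 ± 415 against 77.5 ± 41.6, log2 4.04, adjusted p = 0.0145) and the vitamin C synthesis gene Gulo (25590 ± 137 against 935 ± 730, log2 5.49, 0.0164) were called with all tumours. They were not called without β-catenin tumour 1 (adjusted p = 0.0689 and 0.0664) or 2 (0.0573 and 0.0893), which leaves 1 tumour in that group, assumed to vary like the others.

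Among set 1 lucOS tumours 11 lists were called at the preset correlation and 0 of these with an estimated one (adjusted p = 0.0581 to 0.661). Of the Wnt targets 4 of 12 were higher and 0 lower (6 over the list alone, median 1.69, camera adjusted p = 1.86e-05), and of the pericentral genes 5 of 13 were higher (9 over the list alone, median 2.76, adjusted p = 2.76e-09). The p53 targets had 1 of 20 higher (6 over the list alone, median 0.909, adjusted p = 6.27e-06), and mature hepatocyte genes 0 of 17 (median 0.529, adjusted p = 0.0018). Cell cycle genes had 2 of 20 lower and 0 higher (9 over the list alone, median -0.928, adjusted p = 6.27e-06). Cytotoxic and NK cell genes had 1 of 13 lower (6 over the list alone, median -1.90, adjusted p = 0.00113). T cell markers were lower as a list (1 of 15 lower, median -1.26, adjusted p = 0.0268), and so were neutrophil markers (0 of 10, median -2.21, adjusted p = 0.0268). Fetal liver genes (1 of 12 lower, median -2.11, adjusted p = 0.0268) and bile duct markers (1 of 8 lower, 3 over the list alone, median -1.93, adjusted p = 0.00872) were lower, and endothelial markers were higher (0 of 13, median 0.712, adjusted p = 0.0156). Without p53 tumour 1 the T cell (0.178) and endothelial (0.105) calls were lost, and without p53 tumour 2 the neutrophil call (0.133). Without β-catenin tumour 1 the neutrophil (0.504) and bile duct (0.0709) calls were lost, and without β-catenin tumour 2 the T cell (0.18), endothelial (0.813) and fetal liver (0.0576) calls. TMM added periportal (0.0428), MHC class II (0.0428) and interferon γ genes (0.049), which were not called as deposited (medians -0.976, -1.21 and -0.869, adjusted p = 0.0827 each). No list call was made for checkpoint (adjusted p = 0.137), dendritic (0.5), B cell (0.13), chemokine (0.244), MHC class I (0.313), stellate (0.13), ribosome biogenesis (0.0669), lipid synthesis (0.0669) and red blood cell genes (0.351). Macrophage markers (median -0.0591, turning to 0.0874 under TMM, adjusted p = 0.892) and type I interferon genes (median -0.0854, turning to 0.0607 under TMM, adjusted p = 0.386) were not called, and for both the camera test pointed upward. The 4 acinar genes had a median of 0.473 and a mean of -0.0873. Ccl5 was not called (30.4 ± 1.05 against 104.5 ± 83.7, log2 -1.40, adjusted p = 0.251).

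In this lucOS comparison of set 1 limma called 678 of 16108 genes, 261 higher and 417 lower with β-catenin, but only 19, 12 higher and 7 lower, when the 2 groups compared were fitted alone. TMM called 514, 317 higher and 197 lower, of which 458 were shared. By edgeR 418 genes were called and by DESeq2 2031. The count was 76 without β-catenin tumour 2, 121 without β-catenin tumour 1, 207 without p53 tumour 1 and 219 without p53 tumour 3.

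Among lucOS tumours of set 2, 3 β-catenin tumours were compared with 4 p53 tumours. Axin2 (692 ± 349, n = 3, against 8.08 ± 4.06, n = 4; log2 6.28, adjusted p = 0.000271) and the Wnt-induced receptor gene Lgr5 (264 ± 101 against 1.98 ± 1.39, log2 6.51, adjusted p = 0.000101) rose with β-catenin. Among genes called lower, the T cell receptor component Cd3g stood at 6.69 ± 3.55 against 59.4 ± 11.2 (log2 -3.04, adjusted p = 0.00757) and the cytotoxic cell regulator Eomes at 1.62 ± 1.47 against 32.7 ± 9.69 (log2 -3.77, adjusted p = 0.00378). The NK receptor Klrd1 stood at 5.37 ± 2.68 against 49.5 ± 8.68 (log2 -3.06, adjusted p = 0.0046) and the PD-1 ligand gene Pdcd1lg2 at 0.517 ± 0.450 against 34.9 ± 12.1 (log2 -4.56, 0.00159). Scgb1a1, an airway secretory protein gene, rose to 443 ± 31.3 from 0.776 ± 0.529 (log2 8.03, adjusted p = 2.09e-05), and Cdh16 fell to 0.276 ± 0.479 from 1959 ± 1487 (log2 -10.30, 5.71e-05). These calls held with each tumour left out. In the tumours named JAX alone (3 lucOS β-catenin against 1 p53) Axin2, Lgr5 and Scgb1a1 were called, while Cd3g, Eomes, Klrd1, Pdcd1lg2 and Cdh16 did not pass the filter and were not tested. With 1 p53 tumour the spread there comes from the β-catenin groups alone, and the p53 tumour is assumed to vary like them. Dlk1, a fetal liver gene (log2 -8.61, adjusted p = 0.00933), Gzma (10.9 ± 2.53 against 126 ± 52.3, log2 -3.34, 0.00341) and the chemokine Cxcl10 (154 ± 83.8 against 1415 ± 273, log2 -3.30, 0.00207) fell with each tumour left out too. In the tumours named JAX alone they had log2 differences of -8.23, -3.44 and -3.12 (adjusted p = 0.467, 0.207 and 0.266), of similar size but not called. Ccl5 fell to 22.5 ± 4.23 from 148 ± 51.2 (adjusted p = 0.0162), a call lost without β-catenin tumour 3 (0.0516) and in the tumours named JAX alone (log2 -1.92, adjusted p = 0.612).

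In the set 2 β-catenin tumours 9 immune lists were called lower at the preset correlation, and none of these with an estimated one (adjusted p = 0.264 to 0.525). Of the cytotoxic and NK cell genes 13 of 14 were lower and 0 higher (14 over the list alone), with a median of -2.70 and a camera adjusted p = 6.68e-08. Of the T cell markers 11 of 15 were lower (12 over the list alone, median -1.95, adjusted p = 1.12e-05), and of the interferon γ genes 9 of 13 (12 over the list alone, median -1.80, adjusted p = 4.19e-05). Of the MHC class II genes 8 of 10 were lower (10 over the list alone, median -2.29, adjusted p = 1.14e-05), with Cd74 at 1180 ± 522 against 5955 ± 2278. Type I interferon genes had 7 of 18 lower (12 over the list alone, median -1.78, adjusted p = 0.000361). Checkpoint and regulatory T cell genes had 7 of 13 lower (9 over the list alone, median -1.25, adjusted p = 0.000435), with Cd274, the PD-L1 gene, at 128 ± 19.9 against 434.5 ± 183. MHC class I genes had 6 of 15 lower (8 over the list alone, median -0.552, adjusted p = 0.000411), chemokine genes 5 of 19 (12 over the list alone, median -1.84, adjusted p = 0.00102) and dendritic cell markers 3 of 13 (4 over the list alone, median -0.849, adjusted p = 0.0362). In the tumours named JAX alone, over the members kept there and with a single p53 tumour, the cytotoxic (median -2.10, adjusted p = 0.000927) and T cell (median -1.40, 0.00545) lists were called. This rests on the 1 p53 tumour varying like the others, since 4 splits allow no exact p under 0.25. The checkpoint (0.143), type I interferon (0.189) and dendritic (0.65) lists were not called there. The dendritic call was also lost without p53 tumour 2 (0.118) or β-catenin tumour 1 (0.0511) or 3 (0.0559). B cell markers (1 of 8 lower, adjusted p = 0.12), neutrophil markers (3 of 10 lower, adjusted p = 0.339) and macrophage markers (2 higher and 4 lower of 16, median -0.609 but mean 0.202, adjusted p = 0.607) were not called as lists. The mean cytotoxic score was 2.78 ± 0.24 (SD, n = 3) against 5.52 ± 0.26 (n = 4) without overlap (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow, Benjamini-Hochberg adjusted 0.062 over the lists).

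Tumour cell lists of set 2 included the Wnt targets, with 6 of 11 higher (7 over the list alone, median 3.06, camera adjusted p = 6.68e-08), and the pericentral genes, with 6 of 13 higher (7 over the list alone, median 3.49, adjusted p = 6.68e-08). Both held with an estimated correlation (0.0461 and 0.0108). The p53 targets had 6 higher and 1 lower of 20 (7 and 1 over the list alone, adjusted p = 0.000804; adjusted p = 0.39 with an estimated correlation). Cell cycle genes had 6 of 20 lower (11 over the list alone, median -0.909, adjusted p = 8.52e-05; 0.543 estimated), with the topoisomerase gene Top2a at 6920 ± 3456 against 22110 ± 4401. Mature hepatocyte genes had 2 of 17 higher (2 over the list alone, median 0.42, adjusted p = 0.0242; 0.601 estimated), a list call lost under TMM (0.0642), without p53 tumour 1 (0.0955), β-catenin tumour 2 (0.0519) or 3 (0.0971) and in the tumours named JAX alone (0.412). Periportal genes had 1 of 12 higher, with a median of -0.274 while the test pointed upward (adjusted p = 0.524). Fetal liver (1 higher and 2 lower of 11, adjusted p = 0.272), bile duct (1 of 7 lower, adjusted p = 0.857) and stellate cell genes (3 of 15 higher, adjusted p = 0.12) were not called as lists. Ribosome biogenesis (1 of 19 lower, adjusted p = 0.488), lipid synthesis (2 of 13 higher, adjusted p = 0.12) and red blood cell genes (0 of 7, adjusted p = 0.12) were not called either. Endothelial markers (2 of 13 lower, adjusted p = 0.857) had a median of -0.131 that turned to 0.0249 under TMM, and a mean of 0.0715. The 3 acinar genes had a median of -0.0885.

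Over all genes of the set 2 lucOS comparison limma called 2656 of 15625, 950 higher and 1706 lower with β-catenin, and TMM called 2344, 1321 higher and 1023 lower, of which 1973 were shared. By edgeR 2230 genes were called and by DESeq2 3842. Without p53 tumour 1 the count was 1232, without p53 tumour 2 1708, without p53 tumour 3 1127 and without β-catenin tumour 3 1222. In the tumours named JAX alone, genes high only in p53 tumours could not pass the filter, since 1 p53 tumour is left. Numbers of higher and lower genes are therefore not compared there. Since 3 of the 4 p53 tumours and none of the β-catenin tumours have names beginning with AL, name prefix and driver are nearly confounded in set 2.

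**Figure D2:**
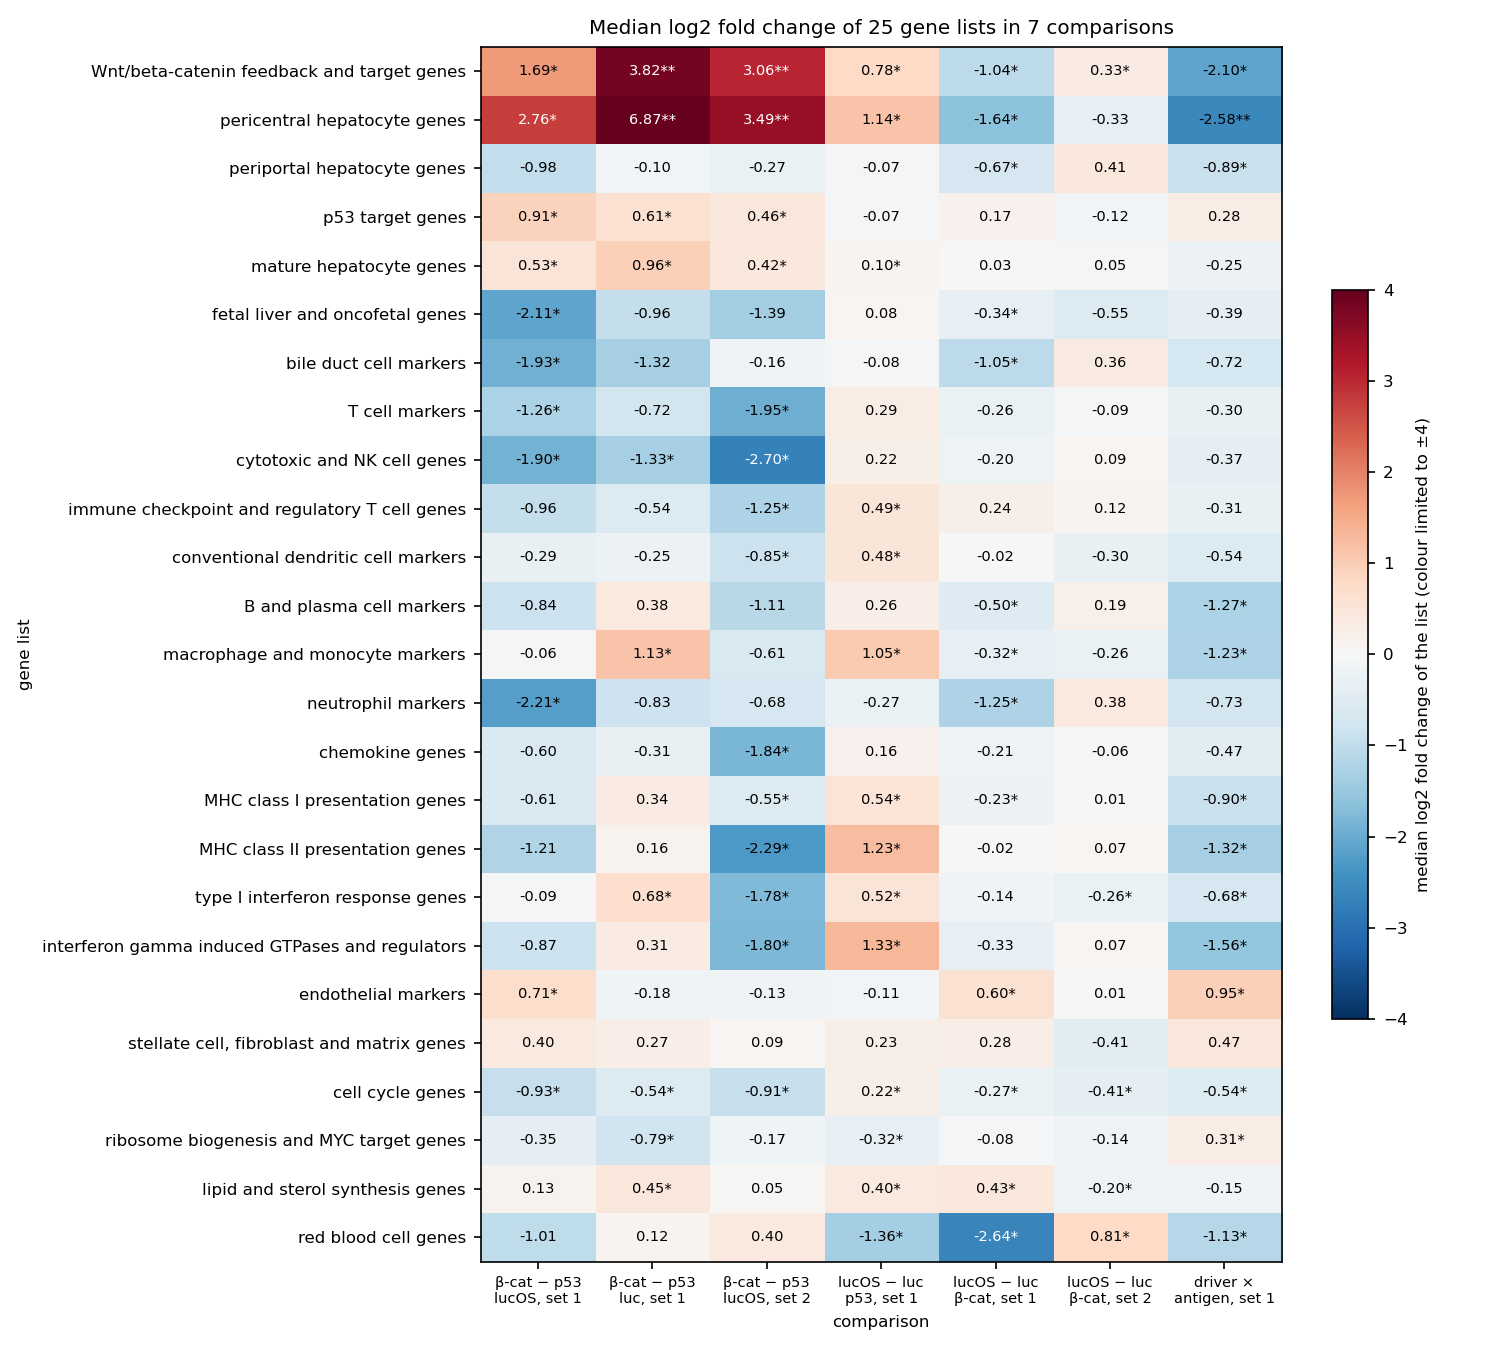
Median log2 difference of 25 gene lists (vertical) in the 7 comparisons (horizontal), as a colour limited to 4 in each direction. One star marks a camera adjusted p under 0.05 and a double star one that also held with an estimated correlation; the double stars lie in the Wnt target and pericentral lists.

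**Figure D3:**
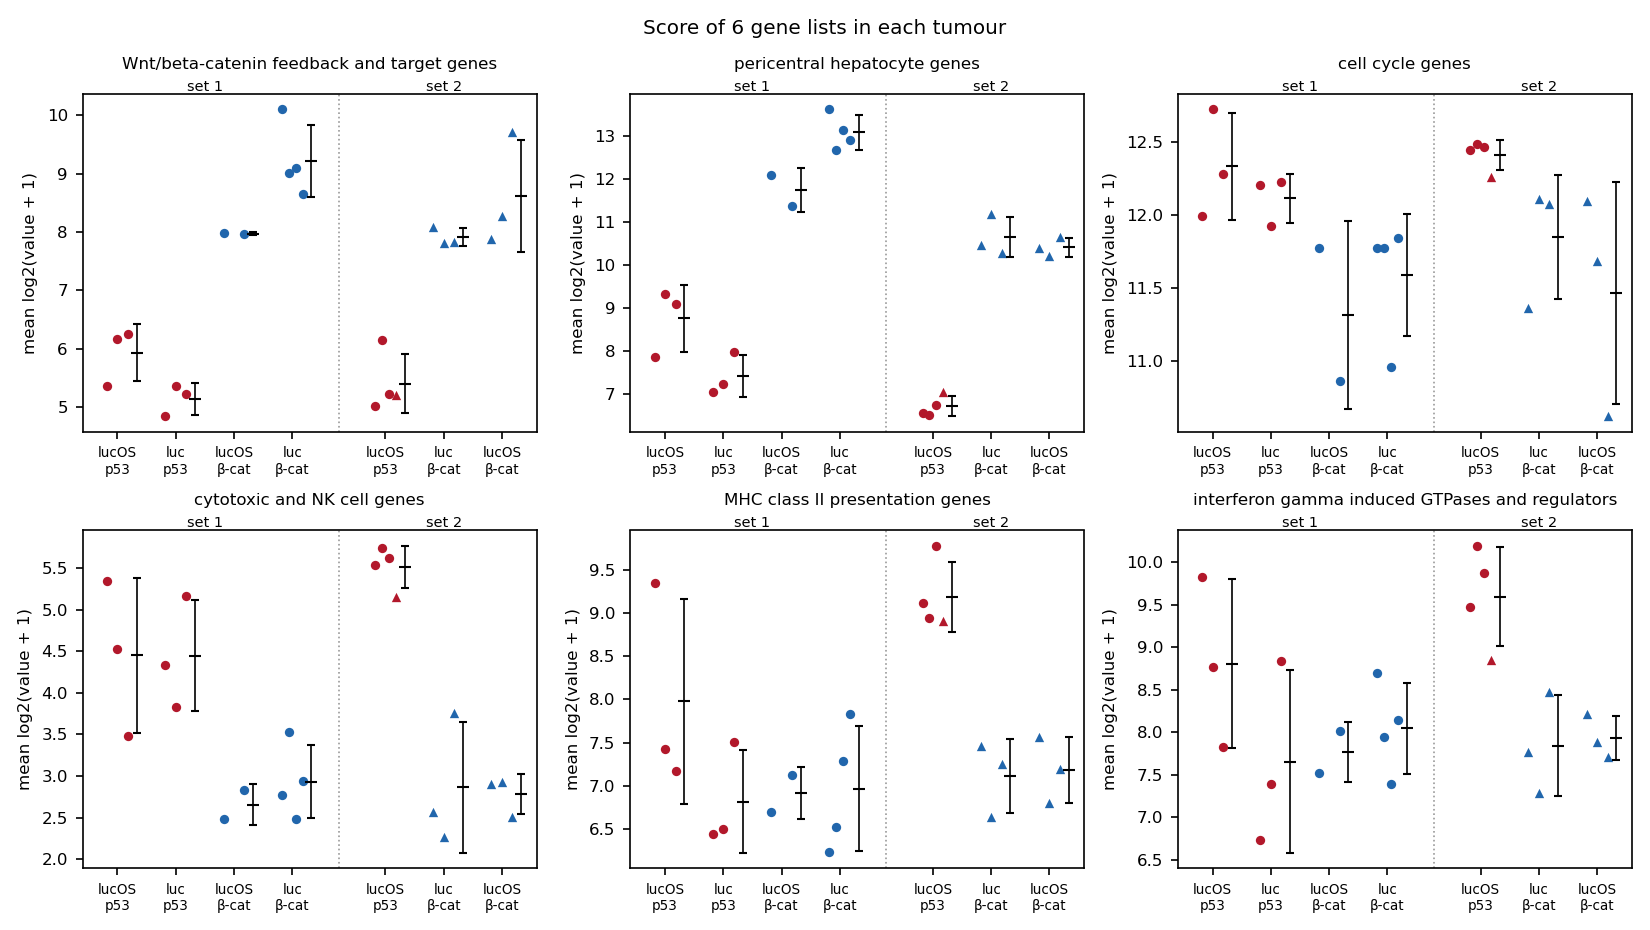
Mean log2 value per tumour (vertical) of 6 gene lists, by group. Circles are tumours with names beginning with AL, triangles JAX, and the dash and bar are the mean ± SD; the cytotoxic scores of set 2 averaged 2.78 in lucOS β-catenin and 5.52 in lucOS p53 tumours.

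The lucOS driver differences of both sets were compared over the 15378 genes kept in both. Across genes, which are not independent replicates, their log2 differences had Pearson's r = 0.675 and Spearman's rank correlation = 0.596, with r from 0.591 to 0.683 when any tumour was left out. Of the genes, 657 were called in set 1 and 2613 in set 2, and 407 in both, all in the same direction. Of these, 168 were higher, where independent calls would share 15.5, and 239 were lower, where they would share 43.9. Genes called in set 1 had the same sign in set 2 in 98.9% of cases, against 73.9% over all genes.

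**Figure D4:**
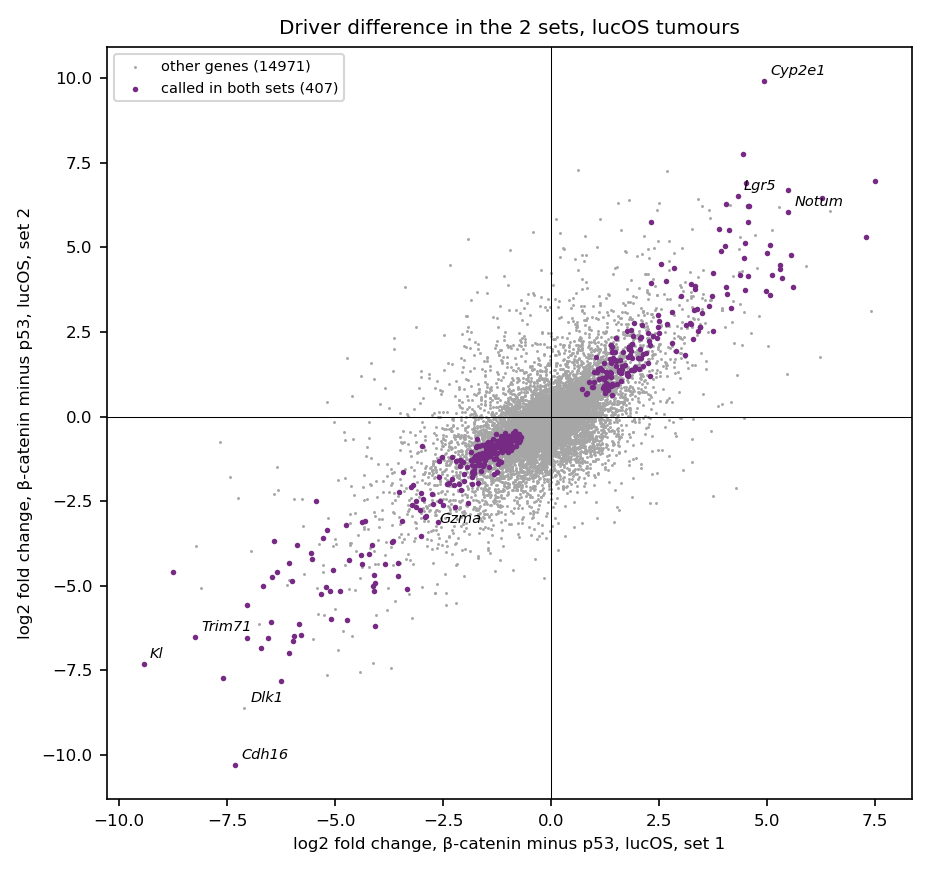
Log2 difference of β-catenin minus p53 among lucOS tumours in set 1 (horizontal) and set 2 (vertical) for 15378 genes. Each point is a gene; the 407 genes called in both sets lie at the lower left and the upper right.

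Within p53 tumours of set 1, 3 lucOS and 3 luc tumours were compared to see what the antigen changes. The camera test at the preset correlation called 14 lists, of which 0 were called with an estimated correlation (adjusted p = 0.386 to 0.842). At the preset correlation interferon γ genes, which T cell and NK cell activity induces, were higher as a list with lucOS (median 1.33, camera adjusted p = 1.33e-06), with the GTPase gene Iigp1 at 2587 ± 1037 (n = 3) against 844 ± 508 (n = 3). MHC class II genes (median 1.23, adjusted p = 7.79e-06) and macrophage markers (median 1.05, adjusted p = 2.97e-05) were higher too. MHC class I genes were higher (median 0.541, adjusted p = 0.00039), with H2-K1 at 17040 ± 7616 against 9081 ± 3610. Pericentral genes were also higher (median 1.14, adjusted p = 4.36e-06), with Cyp2e1 at 2931 ± 836 against 954 ± 491, and 3 of these 13 genes passed when adjusted over the list alone. In limma 0 of 16108 genes were called, with 722 at an unadjusted p under 0.05, 0 by edgeR and 9 by DESeq2, so none of the named members was called (limma adjusted p = 0.952 each). Ccl5 was not called (104.5 ± 83.7 against 84.7 ± 51.2, log2 0.13), nor was Trp53 (log2 -0.16). Further called lists were type I interferon (median 0.524, adjusted p = 0.00118), Wnt targets (median 0.782, or 0.621 with a gene at 0 set to its bound, adjusted p = 0.00205) and lipid synthesis genes (0.397, adjusted p = 0.00246), all higher. Mature hepatocyte (0.1, adjusted p = 0.0332), cell cycle (0.223, adjusted p = 0.0344), dendritic (0.477, adjusted p = 0.0383) and checkpoint genes (0.49, adjusted p = 0.0432; 0.0515 under TMM) were higher too, and ribosome biogenesis (-0.319, adjusted p = 0.00039) and red blood cell genes (-1.36, adjusted p = 0.00791) were lower. T cell markers (median 0.294, adjusted p = 0.437) and cytotoxic genes (median 0.222, adjusted p = 0.914) were not called. The interferon γ, pericentral, MHC class I, MHC class II, Wnt, lipid and ribosome calls held with each tumour left out. Without lucOS tumour 1, however, the MHC class II median fell to 0.484 (adjusted p = 0.0336) and the interferon γ median to 0.704, so much of the class II rise rests on this tumour (Cd74 15220, against 2246 and 1328 in the other lucOS and 849.9 to 2357 in luc tumours). Without lucOS tumour 1 the checkpoint (0.466), dendritic (0.239), mature hepatocyte (0.43) and red blood cell (0.257) calls were lost. Without lucOS tumour 2 the type I interferon (0.0789), checkpoint (0.0834), mature hepatocyte (0.0998) and cell cycle (1) calls were lost, and without lucOS tumour 3 the dendritic (0.111), red blood cell (0.111) and cell cycle (0.0881) calls. Leaving out luc tumour 1 ended the macrophage (0.193), type I interferon (0.153), checkpoint (0.503) and dendritic (0.5) calls. Leaving out luc tumour 2 ended the dendritic (0.101), mature hepatocyte (0.119), red blood cell (0.262) and cell cycle (0.326) calls, and luc tumour 3 the mature hepatocyte call (0.122). Fetal liver genes had a median of 0.0819 and a mean of -0.478, and p53 targets a median of -0.072 and a mean of 0.00166 (neither called).

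Within β-catenin tumours of set 1, 2 lucOS tumours were compared with 4 luc tumours. Of the 13 lists called at the preset correlation, 0 were called with an estimated one (adjusted p = 0.123 to 0.654). At the preset one pericentral genes were lower with lucOS (median -1.64, camera adjusted p = 5.25e-09), with the glutamine synthetase gene Glul at 28250 ± 21280 (n = 2) against 107000 ± 48280 (n = 4), and so were Wnt targets (median -1.04, adjusted p = 5.2e-07), with the feedback gene Nkd1 at 52.3 ± 40.6 against 480 ± 216. Red blood cell genes were lower (median -2.64, adjusted p = 1.52e-10), with Hba-a1 at 422 ± 296 against 2650 ± 1603. When adjusted over the list alone, 5 of 13 pericentral, 1 of 12 Wnt and 5 of 7 red blood cell genes passed, the last counting the identical Hba-a1 and Hba-a2 separately. Over all genes limma called 0 of 16108, with 222 at an unadjusted p under 0.05, 0 by edgeR and 18 by DESeq2. Ccl5 was not called (30.4 ± 1.05 against 35.7 ± 4.36, log2 -0.22). Other called lists were periportal (median -0.669, adjusted p = 1.62e-05), neutrophil (-1.25, adjusted p = 0.000339), cell cycle (-0.273, adjusted p = 0.000928) and B cell (-0.501, adjusted p = 0.00551) markers, all lower. Bile duct (-1.05, adjusted p = 0.00725), fetal liver (-0.341, adjusted p = 0.00976), macrophage (-0.319, adjusted p = 0.00976) and MHC class I genes (-0.228, adjusted p = 0.0185) were lower too, and endothelial (0.598, adjusted p = 0.00369) and lipid synthesis genes (0.43, adjusted p = 0.00385) were higher. The red blood cell, pericentral and Wnt calls held with each tumour left out. Without lucOS tumour 1 the periportal (0.0934), fetal liver (0.106), bile duct (0.77), B cell (0.444) and neutrophil (0.918) calls were lost, and the test turned its direction for macrophage (0.874), MHC class I (0.874) and lipid genes (0.642). Without lucOS tumour 2 it turned for endothelial (0.211) and cell cycle genes (0.0437, then called higher), and the fetal liver call was lost (0.157). Leaving out luc tumour 1 ended the MHC class I (0.101) and lipid (0.158) calls, and luc tumour 2 the fetal liver call (0.0536). Leaving out luc tumour 3 ended the bile duct (0.0531) and macrophage (0.153) calls, and luc tumour 4 the bile duct (0.12), B cell (0.0994), macrophage (0.0519) and MHC class I (0.134) calls. Cytotoxic (median -0.195, adjusted p = 0.132) and T cell genes (-0.261, adjusted p = 0.276) were not called, and the mature hepatocyte median of 0.0298 turned to -0.00918 when log values were centred.

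Within β-catenin tumours of set 2, 3 lucOS tumours were compared with 3 luc tumours. The preset correlation gave 5 called lists and an estimated one 0 of these 5 (adjusted p = 0.673 to 0.87). At the preset one red blood cell genes were higher with lucOS (median 0.809, camera adjusted p = 1.02e-05), with Hba-a1 at 2293 ± 761.9 (n = 3) against 1277 ± 206 (n = 3), the opposite direction to set 1, and Wnt targets were higher (median 0.329, adjusted p = 0.0062), again opposite to set 1. Cell cycle (median -0.406, adjusted p = 1.02e-05), lipid synthesis (-0.202, adjusted p = 0.0062) and type I interferon genes (-0.258, adjusted p = 0.0362) were lower. The fatty acid desaturase gene Scd1 stood at 24130 ± 4215 against 63820 ± 7493 and the oncofetal RNA-binding gene Lin28b at 437 ± 360 against 23.2 ± 35.3; each passed only when adjusted over its list alone. In limma 0 of 15625 genes were called, with 288 at an unadjusted p under 0.05, 0 by edgeR and 10 by DESeq2. Ccl5 was not called (22.5 ± 4.23 against 24.7 ± 23.7, log2 0.24). The red blood cell call held with each tumour left out. Without lucOS tumour 3 the cell cycle list turned upward (median 0.0165), and the Wnt (0.439), lipid (0.393) and type I interferon (0.408) calls were lost. The lipid call was also lost without luc tumour 2 (0.2) or 3 (0.0587), and the type I interferon call without lucOS tumour 1 (0.0862) or luc tumour 3 (0.571, median 0.0703). Pericentral (median -0.325, adjusted p = 0.414) and T cell genes (median -0.0904, adjusted p = 0.593) were not called. Across the genes kept in both sets the antigen differences of β-catenin tumours had Pearson's r = 0.0323 and Spearman's rank correlation = 0.0561, with r from -0.0437 to 0.143 when a tumour was left out. Median and mean differed in sign for cytotoxic (0.091 and -0.0828), fetal liver (-0.545 and 0.323), mature hepatocyte (0.0505 and -0.0353), MHC class I (0.00832 and -0.0257), endothelial (0.00596 and -0.00791) and acinar genes (0.286 and -0.492), none of them called.

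Whether the driver difference depended on the antigen was tested in set 1 as an interaction. Pericentral genes had a smaller β-catenin difference with lucOS than with luc (median of the difference -2.58, camera adjusted p = 1.19e-12), and this list held with an estimated correlation (0.0475) and with each tumour left out. Its member Slc22a3, an organic cation transporter gene, had the value -5.51 and was not called by limma (adjusted p = 0.973), but was by DESeq2 (adjusted p = 0.00109). Wnt targets (median -2.10, adjusted p = 2.82e-08; adjusted p = 0.0851 with an estimated correlation) and interferon γ genes (median -1.56, adjusted p = 2.05e-06; 0.538 estimated) were called too and held with each tumour left out. When adjusted over the list alone, 7 of 13 pericentral and 2 of 12 Wnt genes passed, Nkd1 having the value -4.08. Limma called 0 of 16108 genes, with 436 at an unadjusted p under 0.05, 0 by edgeR and 17 by DESeq2. The interaction was not called for T cell (median -0.297, adjusted p = 0.167) or cytotoxic genes (median -0.372, adjusted p = 0.263), nor for Ccl5 (log2 -0.34) or Trp53 (0.02). Set 2 lacks luc p53 tumours, so the interaction could not be tested there. The antigen difference of β-catenin tumours, which enters it, did not repeat in set 2.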

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

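The tests of the name prefix and of the share of tumour cells below were chosen only after the result was seen; the splits of the samples were chosen before.

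In groups of 4 tumours, 11 of the 203 group values tested (151 of genes and 52 of list scores) held 1 tumour far from the others by Dixon's test, where chance gives about 1 in 20, or 10.2. In the luc β-catenin group of set 1, Trp53 was 3689 in tumour 3 (4637 to 4809 in the others), Sds 20.59 in tumour 3 (422.7 to 730.1), Tbx3 1811 in tumour 4 (4637 to 4804), Rhcg 1.707 in tumour 2 and Dao 0.9242 in tumour 4 (both 0 in the others). The cell cycle score of tumour 3 was 10.96 (11.77 to 11.84 in the others) and the lipid synthesis score of tumour 1 was 12.63 (13.56 to 13.63). In the p53 lucOS group of set 2, Myc was 68.45 in tumour 1 (120.5 to 130.3), Scgb1a1 0 in tumour 1 (0.92 to 1.188), Cd3g 42.77 in tumour 4 (63.48 to 66.62) and Cxcl12 6314 in tumour 4 (9041 to 9166). Tumour 4 is the only p53 tumour of set 2 whose name begins with JAX. The Rhcg, Dao and Scgb1a1 values all lie under the floor of 3 reads, so these flags say nothing about the tumours.

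At the preset correlation, the interaction test of camera called a driver difference that depended on the antigen for 13 lists in set 1. Limma called 0 of 16108 genes for this interaction. The median difference with lucOS minus that with luc was -2.58 for pericentral genes, -2.10 for Wnt targets, -1.56 for interferon γ genes, -1.32 for MHC class II, -1.27 for B cell markers, -1.23 for macrophage markers, -1.13 for red blood cell genes, -0.9 for MHC class I, -0.885 for periportal genes, -0.683 for type I interferon genes and -0.537 for cell cycle genes, and it was 0.307 for ribosome biogenesis genes and 0.952 for endothelial markers. With an estimated correlation only the pericentral list was called (adjusted p = 0.0475). The pericentral, Wnt and interferon γ lists were called with each tumour left out. Without lucOS β-catenin tumour 1 the macrophage (adjusted p = 0.0569), MHC class I (0.0963), type I interferon (0.102), periportal (0.25), B cell (0.25), ribosome (0.406) and red blood cell (0.321) calls were lost. Without lucOS β-catenin tumour 2 the cell cycle (0.984) and endothelial (0.813) calls were lost, and without lucOS p53 tumour 1 the MHC class II call (0.0573). The periportal, B cell, endothelial, ribosome and red blood cell calls were each lost without at least 3 different tumours in turn. The group of 2 lucOS β-catenin tumours enters every one of these values, and no biological explanation was tested. The difference between lucOS and luc β-catenin tumours did not repeat in set 2 (Pearson's r = 0.0323 across genes). For Wnt targets its direction was opposite there. Set 2 held no luc p53 tumours, so the interaction itself could not be tested again.

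Y-linked genes, which enter no comparison, gave reads above the limit of 3 in 4 libraries of set 2: 8 and 12 in luc β-catenin tumours 1 and 2, and 5 and 7 in lucOS β-catenin tumours 1 and 3. Xist was high in these tumours as in all others, and where these reads came from was not tested.

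The number of genes that differ between drivers was compared over all 35 splits of the tumours. Among luc tumours of set 1, the real split called 2431 genes and every other split at most 84. Among lucOS tumours of set 2, the real split called 2656 genes and every other split at most 22, in the split that follows the name prefix. In each, 1 of 35 is the smallest share the splits allow, so chance is unlikely but not excluded. A split cannot tell the driver from anything that coincides with it. For the antigen comparisons of p53 tumours in set 1 and of β-catenin tumours in set 2, the 10 splits are too few for a share under 0.05. In both, all 10 splits gave at least the real count of 0, with at most 55 in another split in p53 tumours and 331 in β-catenin tumours. The split with 331 set luc tumour 1 with lucOS tumours 1 and 3, a grouping that follows neither label. This split was the highest of the 9 others, and whether it reflects a structure of these samples was not tested.

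Cytotoxic and NK cell genes were lower with β-catenin in each driver comparison. The labels do not say what the name prefix marks. All names in set 1 begin with AL, so the prefix cannot be the cause there. A difference in animal source among tumours named AL was not tested. The score of set 1 differed by -1.66 between β-catenin and p53 tumours with the antigen as stratum (stratified exact permutation p = 0.00571 over 350 arrangements). In set 2, prefix and driver cannot be told apart by this test: among the tumours named JAX the difference was -2.37, with exact p = 0.25, the smallest that 4 splits allow. A larger share of tumour cells would lower endothelial and stellate cell genes alike, but the cytotoxic score relative to those differed by -3.09 in set 2 (exact p = 0.0286 over 35 splits). The cytotoxic list was not called with an estimated correlation in any driver comparison. Whether β-catenin tumours hold fewer cytotoxic cells or lower expression per cell was not tested, and the explanation remains open.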

How the results depend on the processing

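Averaging a gene's transcripts and centring the log values were chosen only after the results were seen; all other alternatives here were planned. The number of genes called for lucOS in set 1 (678) was 19 when only the 2 groups compared were fitted (16 of the 19 shared), 418 by edgeR and 2031 by DESeq2. The same restricted fit called 2554 genes for luc in set 1, against 2431, and 2376 for lucOS in set 2, against 2656. Why the count fell so far for lucOS in set 1 was not tested. In set 2 the lucOS count of 2656 was 23 in the tumours named JAX alone, where 1 p53 tumour is left. DESeq2 called 9 genes for the antigen in p53 tumours, 18 and 10 in β-catenin tumours of sets 1 and 2, and 17 for the interaction, where limma called 0, and without a filter 1 gene was called for β-catenin tumours of set 1; the cause was not tested. With an estimated correlation 0, 2, 2, 0, 0, 0 and 1 lists were called for lucOS in set 1, luc in set 1, lucOS in set 2, the antigen in p53 tumours, in β-catenin tumours of sets 1 and 2, and the interaction, against 11, 10, 14, 14, 13, 5 and 13 at the preset one. The estimated setting changes both the correlation and the number of independent units that the test assumes. These effects were not separated. Leaving out each tumour gave 76 to 951, 812 to 1964 and 1127 to 2209 genes in the driver comparisons in the same order and 0 in the other 4, and 10 to 17, 9 to 11, 13 to 15, 10 to 13, 6 to 15, 3 to 9 and 8 to 20 called lists. It also turned the test's direction for some lists; the cause was not tested. For the antigen in β-catenin tumours of set 1, the median ran from -0.961 to 0.285 for macrophage, from -0.439 to 0.172 for MHC class I and from 0.118 to 0.722 for lipid genes, which turned without lucOS tumour 1 (lipid 0.203), and from -0.067 to 1.34 for endothelial, from -0.988 to 1.87 for stellate and from -0.746 to 0.176 for cell cycle genes, which turned without lucOS tumour 2. In set 2 it ran from -0.657 to 0.0703 for type I interferon and from -0.289 to 0.289 for endothelial genes, which turned without luc tumour 3, and from -0.697 to 0.0165 for cell cycle and from -0.327 to 0.155 for ribosome genes, which turned without lucOS tumour 3. For the interaction it ran from 0.172 to 1.41 for endothelial, from -1.02 to 1.82 for stellate and from -0.445 to 0.259 for lipid genes, which turned without lucOS β-catenin tumour 2. Of the 173 called gene results followed through the alternatives, 2378 repeats gave the same direction and call and 471 lost the call with the same direction, 299 of these with 1 tumour left out, 66 in the tumours named JAX alone, 33 in the fit of only the groups compared, 24 by edgeR and 13 under TMM. Of the 80 called list results, 1017 repeats gave the same outcome, 179 lost the call and 8 reversed the direction. The correlation of the lucOS driver differences between sets moved by less than its spread under every pseudocount, filter and TMM. No paired analysis was possible because the labels give the tumours no replicate numbers. Depth limits genes near 0, where a floor of 3 reads per library gives only a lower bound of the fold.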

Other observations

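All tests on the lists and genes in this part were chosen only after their values were seen, except those of kidney tissue and of a single aberrant tumour, which were chosen before.

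Some fatty acid oxidation genes controlled by the nuclear receptor PPARα were higher in β-catenin than in p53 tumours. Of 14 target genes of this receptor, 4 were called higher among lucOS tumours of set 1 (median log2 1.69), 10 among luc tumours (2.42) and 3 among lucOS tumours of set 2 (1.49), and 0 were called lower in each. No list test was made. In set 2 Angptl4 (0.04), Cpt1a (0.11), Creb3l3 (0.22) and Fgf21 (-0.61) were not called by limma. Ehhadh, an enzyme of peroxisomal oxidation, stood at 13520 ± 3137 (SD, n = 2) against 1868 ± 333 (n = 3; limma log2 2.85, adjusted p = 0.00828, but 0.0506 without lucOS β-catenin tumour 1). Among luc tumours it stood at 9979 ± 5096 (n = 4) against 1371 ± 293 (n = 3; 2.76, adjusted p = 0.000884), a call that held with each tumour left out. In set 2 Ehhadh was not called (1.61, adjusted p = 0.0592, or 0.0495 under TMM).

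Raet1 genes, which encode ligands of NKG2D, a receptor by which NK cells recognise stressed cells, were higher in β-catenin tumours of set 2 while cytotoxic genes were lower. Of 6 ligand genes 5 were called higher there (median log2 3.59), all of them Raet1 genes, with Raet1e at 378 ± 73.7 (n = 3) against 30.0 ± 29.5 (n = 4; limma adjusted p = 0.00909), a call that held with each tumour left out, and in the tumours named JAX alone if the single p53 tumour varied like the others. The 6th, Ulbp1, was not called (23.6 ± 9.07 against 46.3 ± 16.1, log2 -0.94). In set 1, 0 of 5 were called among lucOS (median 3.51) or luc tumours (2.55), with Raet1e at adjusted p = 0.101 and 0.106. The Raet1 genes are near-identical copies whose reads cannot be assigned with certainty, so they do not count as independent genes.

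Cdkn2a, which encodes INK4A, an inhibitor of the cell cycle, and also ARF, was higher in p53 tumours. Its value was 2090 ± 2064 (n = 6) in p53 against 43.9 ± 38.6 (n = 6) in β-catenin tumours of set 1, with 5 of 6 p53 tumours above every β-catenin tumour. In set 2 it was 3289 ± 2557 (n = 4) against 54.1 ± 69.1 (n = 6), with 4 of 4 above. The log2 difference was -6.35 among lucOS tumours of set 2 (limma adjusted p = 0.00962, held with each tumour left out, but log2 -4.39 and adjusted p = 0.563 in the tumours named JAX alone, with 1 p53 tumour). Among lucOS tumours of set 1 it was -4.81 and not called (adjusted p = 0.0769, but 0.0242 without p53 tumour 2). The luc difference of -4.60 was called (0.0283), and was lost without p53 tumour 1 (0.114), p53 tumour 2 (0.0968) or β-catenin tumours 1 (0.051), 2 (0.0597) or 4 (0.0589).

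Some kidney and epithelial genes were higher in p53 tumours. Cdh16, a kidney cadherin gene, stood at 1641 ± 1597 (n = 6) against 2.28 ± 3.38 (n = 6) in set 1 and at 1959 ± 1487 (n = 4) against 0.874 ± 0.949 (n = 6) in set 2, and Pax8 at 702.5 ± 506 against 6.22 ± 10.7 and at 845 ± 339 against 6.78 ± 7.35. Of 11 other kidney transcripts, 6 were kept in set 1 and 4 in set 2, and among lucOS tumours of set 1, luc tumours and lucOS tumours of set 2, 0, 1 and 1 were called higher in p53 tumours. Kidney tissue in the samples would bring its abundant transcripts along, but the highest mean of Umod, Kap, Slc34a1, Miox and Slc12a1 in p53 tumours was 1.14% of that of Cdh16 in 1 set and 0.446% in the other, and Kap was 0 in every tumour. Other kidney tubule genes were present, with Lrp2 at 794 ± 1137 against 17.8 ± 14.8 and 1360 ± 643 against 80.3 ± 125, and Slc22a6 at 409 ± 388 against 55.4 ± 109 and 721 ± 488 against 373 ± 530. Slc5a2 was present too but not higher in p53 tumours (516 ± 123 against 568 ± 85.4 and 439 ± 139 against 670 ± 120). Slc12a1 reached 600.7 in a β-catenin tumour of set 2, against a mean of 0.228 in p53 tumours. High Cdh16 was not confined to a single tumour per set, since 10 of 10 p53 tumours lay above the highest β-catenin tumour of their set. In set 1 the margin was small, with the lowest p53 tumour at 12.94 and the highest β-catenin tumour at 9.065. Because Cdh16 was picked for its difference between drivers, this count is no independent test of that difference. For Pax8, 5 of 6 did in set 1 and 4 of 4 in set 2. Which cells produced these transcripts was not tested.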
